A study of Sparus aurata with 4 samples.

How the data were processed

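Adipose tissue RNA of gilthead sea bream (Sparus aurata) was measured on 4 two-colour Agilent oligonucleotide arrays, which the files place on 1 slide and in 1 scan. Juvenile fish of 16 g starting weight had been kept in 9 tanks of 60 fish and fed 1 of 3 diets. The CTRL diet held fish oil. In the 66VO diet a blend of vegetable oils took the place of 66% of the fish oil, and in the VO diet of 100%. Per the labels' protocols, total RNA was pooled within each diet and 250 ng was labelled with Cy3 or Cy5. One pair of arrays set the 66VO pool against the CTRL pool and the other pair set the VO pool against the CTRL pool. Array 1 of each pair carried the diet pool in Cy5 and array 2, the dye swap, carried it in Cy3.

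The deposited scanner tables hold, per the file headers, mean spot intensity and median local background intensity for each channel, with flags for outliers, saturation and signals well above background, all written by Agilent Feature Extraction 9.5.3. They also hold that program's processed signals, which are background-subtracted and dye-normalised intensities, the log10 ratio of Cy5 over Cy3 and, per the file headers, an error-model p-value that covers spot error on that array only. The authors' deposited value table of the same arrays was set against the scanner values. As deposited by the authors, it holds the log2 ratio of the processed signals with the dye-swapped arrays already turned to diet over CTRL, and 99.7% of the 15057 values of each array lay within 0.01 of that ratio. Its scale and direction as a ratio of the processed signals are therefore settled. With the program's own log ratio the deposited values correlated at 1 on each 66VO array, but at 0.71 and 0.91 on VO arrays 1 and 2. The reason for the lower values was not tested. The medians of its columns were -0.084 and 0.067 for the 66VO arrays and -0.112 and 0.078 for the VO arrays, so that no further centring was visible.

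Each array held 14999 probe spots, each with its own probe name and a length of 60 nt, and 536 control spots. The probes stand for 6871 contigs, which are assembled transcript sequences. The files pair no gene names with the probes, and 0 of the 6871 contig identifiers matched the gene table of the sea bream reference. Probes are therefore reported by probe and contig identifier with their sequence, and no genome position is given. The 24 gene lists fixed before the data were examined (lipid metabolism, immune, stress and tissue marker lists among them) need gene names and were not used here.

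In limma 3.58.1 (R 4.3.3), mean intensities were background-corrected by normexp with an offset of 50, each array's log2 ratios were normalised by loess with control spots at weight 0, and ratios were turned to diet over CTRL. A probe was compared where it was well above background in at least 1 channel on each array used and flagged as non-uniform on none of them. This left 10337 probes for 66VO against CTRL, 9955 for VO against CTRL and 9558 where all 4 arrays were used. Between 55.4% and 75.6% of the probes were well above background in a channel, and at most 10 probe spots of a channel were saturated. The number of arrays limits the precision.

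Each diet was represented by 1 RNA pool, and the arrays of a dye swap repeat the same RNAs, so there are no residual degrees of freedom among samples and no p-value is given. A probe was called higher or lower by a rule of size, namely a difference of at least 1.5-fold in the same direction on both arrays of the pair. Probes that passed the limit in opposite directions on the 2 arrays were counted beside each result, since they reflect dye bias and array noise. SD values of a probe are over the 2 arrays of a pair and measure technical spread only. For differences across the 2 pairs they are over the 2 dye orientations. VO was set against 66VO by the difference of their ratios within each dye orientation. The rule for named probes took, for each of these 3 comparisons, the 2 probes with the highest and the 2 with the lowest mean log2 ratio among the called ones, counting a contig once. These choices were made before the data were examined.

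After the data were seen, channel levels of the same dye were also compared across arrays (after loess and Aquantile normalisation between arrays), since the RNA labelled CTRL differed between the 2 pairs. In these comparisons both dyes had to pass the limit. On simulated data made from 14999 probes with known changes, the rule recovered 24% of the probes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 3-fold or 4-fold for VO against CTRL, and 18%, 90%, 100% and 100% for 66VO against CTRL. It called 4 and 3 of 9392 unchanged probes, and 27 and 34 were opposed. For each comparison 50 probes were changed at each fold, with levels and noise taken from the VO arrays. So few changes do not stand for the 66VO pair, where 52.7% of the compared probes were called. Alternatives tried were Feature Extraction's processed signals, the authors' value table, a normexp offset of 16, no background correction, median centring without loess, Aquantile, no filter on dim probes, a stricter filter, other limits of size, each array left out and, chosen after seeing the data, quantile normalisation over all channels and, for 66VO against VO, of the diet channels alone.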

Results

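Transcript levels in adipose tissue of gilthead sea bream were measured in RNA pools of fish fed fish oil (CTRL), a diet with 66% of the fish oil replaced by vegetable oils (66VO) or a diet with all of it replaced (VO). The comparisons ask which transcripts differ when vegetable oils take the place of fish oil. There were 4 arrays, 2 for 66VO against CTRL and 2 for VO against CTRL, each pair being a dye swap of the same RNAs. The median raw probe signal was 186 in Cy5 and 220 in Cy3 on 66VO array 1, and 386 and 118.5 on 66VO array 2. On the VO arrays it was 161 and 110.5 for array 1, and 142.5 and 113 for array 2. The local background medians were 49 to 50.5 in Cy5 and 34 to 38 in Cy3. Every value below rests on 1 RNA pool per diet, so no difference has a replicate check between fish or tanks.

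The RNA labelled CTRL was not alike on the 2 pairs of arrays. The RNA labelled CTRL on the 66VO arrays (66VO-array CTRL RNA) gave channel levels that correlated with each other at r = 0.998 across 9558 probes, which are not independent replicates. With the other 6 channels it correlated at 0.865 to 0.89. The other 6 channels, which held 66VO, VO and the RNA labelled CTRL on the VO arrays (VO-array CTRL RNA), correlated with one another at 0.985 to 0.997. Compared in the same dye, 2464 probes were higher and 3078 lower in the 66VO-array CTRL RNA than in the VO-array CTRL RNA, 58.0% of the probes compared, and 4 were opposed. The SD of this difference across probes was 1.32 on the log2 scale. There were 587 probes well above background in both channels of the 66VO-array CTRL RNA and in neither 66VO channel, against 3 for the VO-array CTRL RNA and VO. The reverse counts were 19 for 66VO and 16 for VO. On both 66VO arrays the channel labelled CTRL had the higher raw median (220 against 186, and 386 against 118.5). These counts may thus partly reflect signal strength. Each ratio of 66VO over CTRL below is therefore a ratio over the RNA labelled CTRL on the 66VO arrays.

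**Figure D1:**
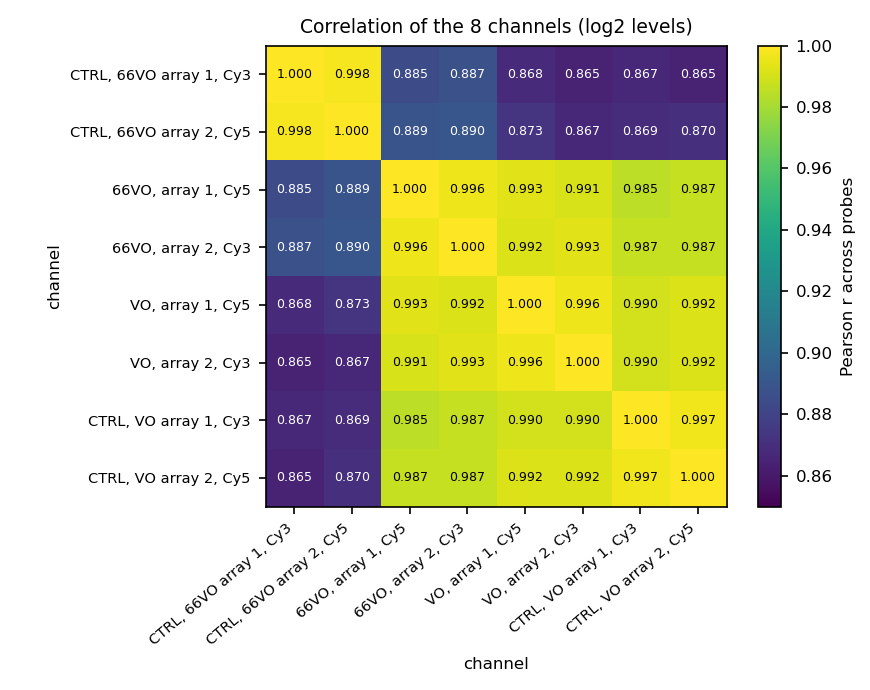
Pearson correlation across 9558 probes between the normalised log2 levels of the 8 channels, with the diet label, array and dye of each channel on both axes. The 2 channels labelled CTRL on the 66VO arrays correlate at 0.998 with each other and at 0.865 to 0.89 with the other 6, which correlate at 0.985 to 0.997 among themselves.

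Between VO and CTRL, 129 probes of 73 contigs were higher in VO and 51 probes of 27 contigs were lower, together 1.8% of the 9955 probes compared, and 20 were opposed. The highest was CUST_66_PI400645798 of contig gsgl01b01i05r1.1.i.sb.1 (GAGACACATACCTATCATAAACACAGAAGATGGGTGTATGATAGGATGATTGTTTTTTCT), with a log2 ratio of 6.42 ± 0.59 (SD, n = 2 arrays), or 85.9-fold. The other 2 probes of that contig gave 6.29 and 6.4, but they share stretches of 58 and 56 nt with it and are no separate check. Next was CUST_1785_PI400645798 of contig sbdietrlp0003e12.f.1.i.sb.1 (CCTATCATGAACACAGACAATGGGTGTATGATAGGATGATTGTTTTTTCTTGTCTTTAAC), with 6.23 ± 0.65, or 75.3-fold. It shares a stretch of 31 nt with CUST_66_PI400645798, and the other 2 probes of its contig gave only 0.4 and 0.54, so the 2 probes need not report separate transcripts. The lowest were CUST_1343_PI401301547 of contig sbdietfadp0008d02.f.1.i.sb.1 (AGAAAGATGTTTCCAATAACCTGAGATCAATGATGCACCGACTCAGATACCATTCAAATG), at -1.72 ± 0.66, and CUST_344_PI400645798 of contig cdn09p0002n21.f.1.i.sb.1 (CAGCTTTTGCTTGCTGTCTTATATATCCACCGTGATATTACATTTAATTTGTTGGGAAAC), at -1.72 ± 0.43, each 3.3-fold lower in VO. The other probes of these contigs gave -1.61 and -1.55 for the former, with 59 nt shared, and -1.39 and -0.88 for the latter, with at most 5 nt shared. With median centring in place of loess CUST_66_PI400645798 gave 7.47, CUST_1785_PI400645798 7.27 and CUST_344_PI400645798 -0.89. With Feature Extraction's processed signals CUST_1785_PI400645798 gave 6.84 and CUST_1343_PI401301547 -2.63.

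Large differences between VO and CTRL ran in 1 direction. There were 14 probes of 8 contigs at least 8-fold higher in VO on both arrays, with mean log2 ratios of 3.57 to 6.42, and 0 at least 8-fold lower. Grouped by contig and by stretches of 15 nt shared between probes, the 14 probes formed 5 groups. The other 7 compared probes of these contigs had log2 ratios of -0.85 to 3.37, with a median of 0.4. Over all called contigs, 37 of 41 further probes were also higher where the called probe was higher, with a median of 0.62, and 20 of 21 were also lower where it was lower, with a median of -0.61. Of those sharing no stretch of 15 nt with a called probe of the contig, 20 of 24 were higher and 12 of 13 lower. Averaged by contig, 61 contigs were higher and 20 lower of 4935, and 11 were opposed. Across all probes the ratios of the 2 arrays correlated weakly (Pearson 0.565, Spearman 0.181). The counts depended on the normalisation: with each array centred on its median in place of loess, 2810 probes were higher and 7 lower, and 129 and 2 of these were among those called with loess. Feature Extraction's processed signals gave 308 and 168. By the limit on a single array, 258 were higher and 193 lower without VO array 1, and 339 and 187 without VO array 2.

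Between 66VO and the 66VO-array CTRL RNA, 2704 probes of 1365 contigs were higher in 66VO and 2745 probes of 1451 contigs were lower, 52.7% of the 10337 probes compared, and 22 were opposed. The ratios of the 2 arrays correlated at 0.969 (Spearman 0.958), and their SD across probes was 1.25 against 0.295 for VO against CTRL. The highest were CUST_1002_PI400645798 of contig gsgl01b01e01r1.1.i.sb.1 (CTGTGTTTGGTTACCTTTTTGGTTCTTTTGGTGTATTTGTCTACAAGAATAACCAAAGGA), with a log2 ratio of 6.45 ± 0.27 (87.6-fold), and CUST_748_PI401301547 of contig sbdietfadp0004e03.f.1.i.sb.1 (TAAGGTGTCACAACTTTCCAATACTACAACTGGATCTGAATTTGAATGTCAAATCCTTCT), with 4.72 ± 0.06 (26.3-fold). The other 2 probes of the contig of CUST_1002_PI400645798 gave 0.78 and 1.08, and those of the contig of CUST_748_PI401301547 gave 3.59 and 4.46. Both named probes were also higher in VO than in CTRL, at 4.55 and 2.49, and so were the other 2 probes of the contig of CUST_748_PI401301547, at 1.21 and 1.85. Those of the contig of CUST_1002_PI400645798 went the other way, at -0.85 and -0.76. The lowest were CUST_790_PI401301547 of contig cdn07p0006m11.f.1.i.sb.1 (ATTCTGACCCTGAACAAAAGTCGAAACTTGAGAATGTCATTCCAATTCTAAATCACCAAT), at -7.84 ± 0.29 (229-fold lower), and CUST_1432_PI400645798 of contig sbdietradp0007a06.f.1.i.sb.1 (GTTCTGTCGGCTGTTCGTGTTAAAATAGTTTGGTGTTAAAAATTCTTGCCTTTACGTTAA), at -7.03 ± 0.47 (131-fold lower). The other probes of the 2 contigs gave -7.42 and -6.53, and -6.75 and -6.74, the latter 2 with 59 and 58 nt shared with CUST_1432_PI400645798. CUST_790_PI401301547 was well above background in none of the 4 channels of the VO arrays. Among the called probes, 240 of the lower ones were not well above background in 66VO on either array, and 11 of the higher ones were not well above background in the 66VO-array CTRL RNA on either array, so their differences are only bounds. CUST_1002_PI400645798, CUST_748_PI401301547 and CUST_790_PI401301547 gave 5.27, 3.57 and -8.8 with median centring, and 5.69, 3.85 and -9.04 with quantile normalisation over the 8 channels. With Feature Extraction's processed signals CUST_748_PI401301547 gave 5.38 and CUST_790_PI401301547 -8.59. With median centring in place of loess, 1068 probes were higher and 3856 lower. Both settings centre the ratios on the probe spots, so the split between higher and lower is relative to that centre. Spike-in spots, described below, gave a mean log2 ratio of 1.2 on the scale after loess.

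**Figure D2:**
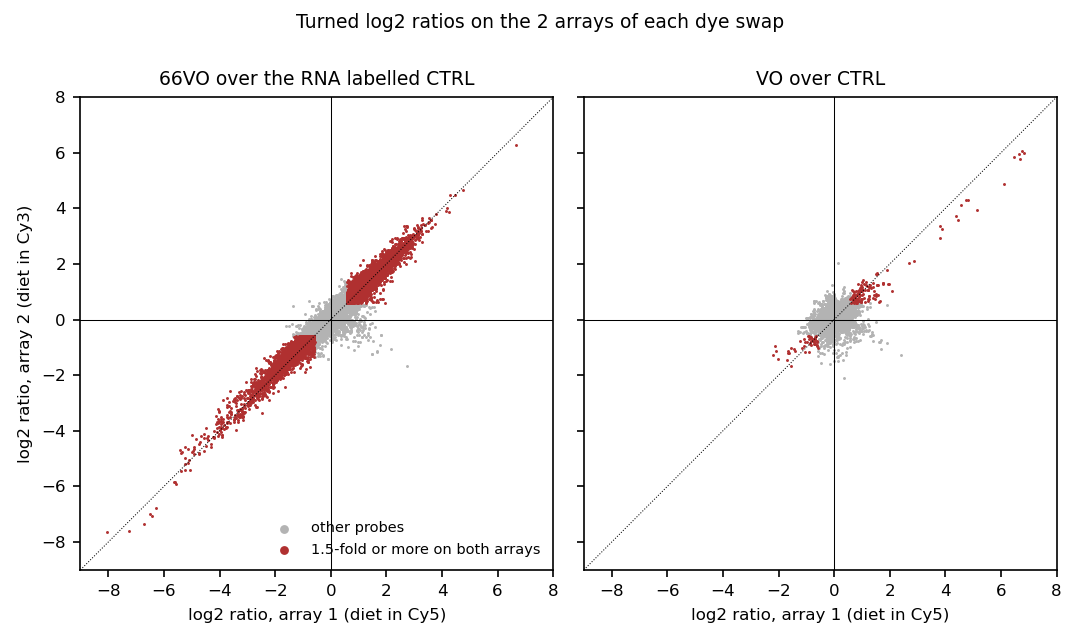
Turned log2 ratio of diet over the RNA labelled CTRL on array 1 (horizontal) against array 2, the dye swap (vertical), one point per compared probe, for 66VO (left, 10337 probes) and VO (right, 9955 probes). Red points passed 1.5-fold in the same direction on both arrays, 2704 higher and 2745 lower for 66VO and 129 higher and 51 lower for VO.

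The 2 sets of ratios correlated weakly across all probes. Over 9558 probes the Pearson correlation of 66VO over CTRL with VO over CTRL was 0.096 and the Spearman correlation -0.016, where 3 exchangeable pools with 1 shared CTRL give 0.5 by simulation. Without VO array 2 the Pearson correlation was 0.056. The covariance was 0.035 against a simulated 0.045. The SDs across probes were 1.23 for 66VO over CTRL, 0.3 for VO over CTRL and 1.23 for VO over 66VO. The simulated 0.5 assumes equal SDs in both comparisons and 1 CTRL RNA, and neither held here. The gap between 0.096 and 0.5 is therefore no measure of a missing shared part. Of the called probes, 123 were higher in both comparisons, where independent lists would share 36.4, and 0 were lower in both, where independent lists would share 12.4. A further 46 probes were higher in 66VO and lower in VO (14.4 for independent lists), and 0 were lower in 66VO and higher in VO (31.4). Whichever way they went in VO, nearly all probes called in VO were higher in 66VO over its own CTRL RNA, namely 127 of the 129 higher ones (median log2 ratio 2.07) and all 51 lower ones (median 1.56).

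Between VO and 66VO, set against each other through their ratios over CTRL, 2524 probes were higher in VO and 2728 lower, 54.9% of the 9558 compared, and 4 were opposed. This difference includes that between the RNAs labelled CTRL. The highest were CUST_1434_PI400645798 of contig sbdietradp0007a06.f.1.i.sb.1 (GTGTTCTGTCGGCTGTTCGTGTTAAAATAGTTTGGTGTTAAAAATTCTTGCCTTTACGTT), at 6.91 ± 0.34, and CUST_802_PI400645798 of contig cdn07p0002e19.f.1.i.sb.1 (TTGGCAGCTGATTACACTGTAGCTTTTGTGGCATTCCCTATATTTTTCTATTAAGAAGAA), at 5.92 ± 0.13. Measured in the same dye, 66VO over VO was 2.75 ± 0.73 for CUST_1434_PI400645798, which is the opposite direction, and -0.79 ± 0.65 for CUST_802_PI400645798, which is the same direction and smaller. The lowest were CUST_736_PI400645798 of contig sbdietrjad0001d02.f.1.i.sb.1 (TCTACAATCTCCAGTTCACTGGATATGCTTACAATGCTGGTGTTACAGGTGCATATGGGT), at -4.11 ± 0.19, and CUST_651_PI401301547 of contig cdn01p0005d20.f.1.i.sb.1 (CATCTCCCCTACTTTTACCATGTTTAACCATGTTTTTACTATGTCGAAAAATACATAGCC), at -4.06 ± 0.17. For these 2 probes 66VO over VO in the same dye was 0.12 ± 0.02 and -0.08 ± 0.02. With median centring CUST_736_PI400645798 gave only -2.41 and CUST_651_PI401301547 only -1.79, and CUST_802_PI400645798 gave 6.87. With median centring in place of loess, 4212 probes were higher in VO and 382 lower.

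Set against each other in the same dye, so that no channel labelled CTRL entered the difference itself, 66VO and VO differed at few probes after loess, a normalisation that does use the CTRL channels. In 66VO, 218 probes were higher and 23 lower than in VO, 2.5% of the 9558 compared, and 1 was opposed. The SD across probes was 0.28. Of the 218 probes higher in 66VO, 203 (93.1%) were also higher in the 66VO-array CTRL RNA than in the VO-array CTRL RNA, against 25.8% of all compared probes. The counts depended on the normalisation: median centring in place of loess gave 32 higher in 66VO and 2333 lower, and Feature Extraction's processed signals gave 404 and 305. With the 66VO and VO channels of one dye quantile-normalised to each other, without any CTRL channel, 178 were higher and 24 lower, 170 and 12 of them among those called after loess. By a single dye, 378 were higher and 156 lower without array 1 of either pair, and 334 and 98 without array 2.

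Set against the VO-array CTRL RNA in the same dye, 355 probes were higher in 66VO and 112 lower, and 5 were opposed. The balance of directions depended on the processing, since Feature Extraction's processed signals gave 642 higher and 781 lower. By a single dye, 316 were lower without 66VO array 1 and 238 without 66VO array 2. The 2 highest and the 2 lowest contigs were those named for VO over CTRL. CUST_66_PI400645798 gave 6.24 ± 0.78 (75.5-fold), CUST_1785_PI400645798 gave 6.03 ± 0.8, CUST_1343_PI401301547 gave -2.18 ± 0.72 and CUST_344_PI400645798 gave -1.9 ± 0.37. Feature Extraction's processed signals gave -3.61 for CUST_1343_PI401301547, and median centring 6.86 for CUST_66_PI400645798. All 129 probes called higher in VO had a log2 difference above 0 in 66VO (0.44 to 6.24, median 0.98), and all 51 called lower had one below 0 (-2.18 to -0.19, median -0.72). The probes called in both comparisons numbered 113 higher and 32 lower, and 0 went opposite ways. Independent lists would share 4.8 and 0.6. With the VO changes taken from the observed ones and 66VO equal to CTRL, the shared CTRL channels gave at most 3 and 2 in 100 simulated draws. On average 60.4% and 65.4% of the called probes then had the same sign in 66VO. These draws called 168.4 probes higher and 92.9 lower in VO on average, more than the 129 and 51 observed. The simulated lists are thus not the same sets as the observed ones. The correlation across probes was 0.709 (Spearman 0.571) with a covariance of 0.084, where unchanged diets against the same CTRL channels give 0.5 and 0.012 by simulation, and part of the excess may come from the shared CTRL channels. At probes selected on VO array 2 alone, the median VO over CTRL log2 ratio on VO array 1 was 0.38 and the median of 66VO over VO in the same dye, in the direction of the VO difference, was -0.038, so that 66VO carried a share of 0.9 of the VO difference. Selection on VO array 1 gave 0.38 and -0.039.

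**Figure D3:**
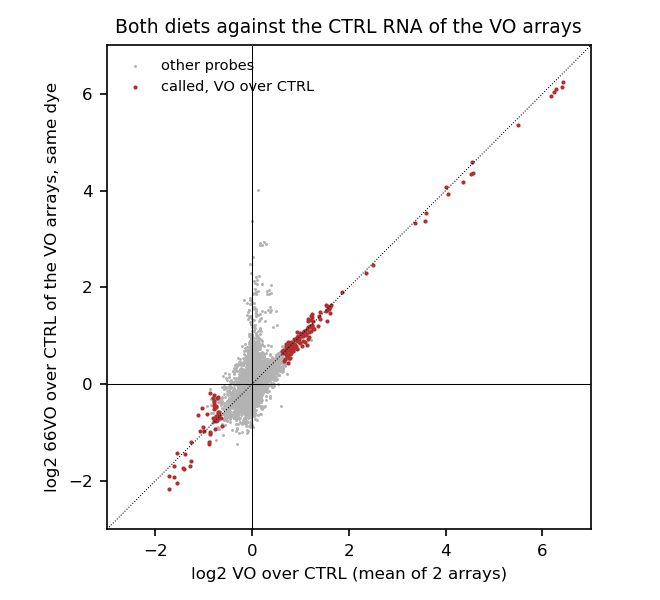
Log2 ratio of VO over CTRL (horizontal, mean of the 2 VO arrays) against the log2 difference of 66VO from the CTRL RNA of the VO arrays in the same dye (vertical, mean of both dyes) for 9558 probes. The red points, 129 probes called higher and 51 called lower in VO, lie near the dotted line of equal values, with 66VO medians of 0.98 and -0.72 against VO medians of 1.04 and -0.8.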

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

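Counts of opposed probes in the ratios over CTRL were set before the data were examined, and the other tests in this part, with the explanations they are used on, were chosen after the results were seen. Of the called probes, 46 were higher in 66VO and lower in VO, each against the RNA labelled CTRL on its own arrays, so that the arrays of the 2 pairs went opposite ways. The difference was not tested, since there is 1 pool per diet. Against the VO-array CTRL RNA all 46 were lower in 66VO too, 29 of them by the 1.5-fold rule, with a median log2 difference of -0.71 (-0.8 in VO). In the 66VO-array CTRL RNA the median was -2.41. The 46 were selected as lower in VO against the same CTRL channels, so part of this agreement is built in. With 66VO equal to CTRL, 65.4% of the probes called lower in VO had the same sign on average by simulation. That simulation called 92.9 probes lower in VO on average, against 51 observed. The direction in 66VO thus changed with the RNA used as CTRL. Spike-in spots, which hold 10 added control sequences and entered no comparison, gave a mean log2 ratio of the 66VO channel over the CTRL channel of 1.2 ± 0.49 (SD over the 10 sequences), against 0.14 ± 0.12 for VO over CTRL, and all 10 sequences were higher on the 66VO pair. With median centring and no loess the values were 1.21 ± 0.05 and 0.09 ± 0.05. A log2 spike-in ratio above 0 means that the RNA in the CTRL channel gave more probe signal for each unit of spike-in signal.

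66VO differed from the RNA labelled CTRL on its own arrays at 52.7% of the probes compared. A diet effect against 1 common CTRL pool is argued against, since 66VO differed far less from the VO-array CTRL RNA in the same dye, with an SD across probes of 0.397 on the log2 scale against 1.25 from the CTRL RNA of its own arrays. An exchange of channel labels on both 66VO arrays is argued against if the VO arrays are labelled correctly, since the RNA labelled 66VO carried a share of 0.9 of the VO difference, where the CTRL pool would carry none. If the VO-array CTRL RNA is itself not typical of the CTRL fish, that argument lapses. Faulty single probes are argued against by the intraclass correlation of 0.909 over probes of the same contig that share no stretch of 15 nt (1715 contigs; 0.951 with all probes, of whose pairs within contigs 62.2% share one). The RNAs labelled CTRL on the 2 pairs did differ, at 58% of the probes compared in the same dye, with 4 opposed. Why they differed, by another RNA in that channel or otherwise, stays open, as no test here bears on it alone.

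In 66VO, 218 probes were higher than in VO in the same dye. Array noise is argued against by the number of opposed probes, 1 against 241 called. Dye bias cancels within a same-dye difference, so opposed probes do not test it here. Carry-over of a constant share of the 66VO-array CTRL RNA, by bleed between channels or by mixing, is argued against as the whole cause only under a condition. Probe response and processing must then leave the apparent share unchanged, which was not tested. Over 83 probes at least 16-fold higher in that RNA, the apparent share had quartiles of 0.74% and 9.33%, and it differed between probes alike in both dyes (Spearman 0.92). Both dyes repeat the same RNAs on the same probes, so this agreement speaks only against array noise as the source of that spread. A carry-over that differs between transcripts and a diet difference between 66VO and VO stay open, the latter untested with 1 pool each. The processing bears on the excess of higher probes too. Their share of the calls was 90.5% after loess and 88.1% with the diet channels alone, but 57% with processed signals and 1.4% with median centring.

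The 180 probes that differed between VO and CTRL exceed what dye bias or array noise would give, since 20 were opposed. Faulty single probes are argued against for the called probes as a set, since 86.5% of the 37 other probes of the same contigs that share no stretch of 15 nt with a called one had the same sign (91.9% of all 62). For the contigs with probes at least 8-fold higher, the 7 other compared probes had a median of only 0.4 (-0.85 to 3.37). Faulty single probes stay open for CUST_1785_PI400645798 (6.23, others of its contig 0.4 and 0.54) and CUST_1002_PI400645798 (4.55, others -0.85 and -0.76). They also stay open for CUST_66_PI400645798, since the other probes of its contig share 58 and 56 nt with it and are no separate check. The same holds for CUST_13_PI401301547, at 5.49, as none of the 7 others exceeded 3.37. The make-up of the pools (fish, tanks or tissue pieces) rather than diet cannot be told apart from diet, since each diet had 1 RNA pool. In the same dye the RNA labelled 66VO carried a share of 0.9 of the difference, but 66VO and VO were there both set against the VO-array CTRL RNA, so the share does not separate diet from the make-up of that RNA.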

How the results depend on the processing

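A count is called kept here when within 1.5 times the value reported, and 97 of 144 counts under other settings were kept. The correlation is called kept when it moved by less than the SD between dye orientations (0.046), as 11 of 12 values did. With 1 array left out it ran from 0.056 (without VO array 2) to 0.119 (without VO array 1). All 124 values of the named probes under settings that apply to them kept their direction, 93 of them within 1 SD, but 22 differed from the reported value by at least 1.5-fold. These tallies include the values with 1 array left out. Such values keep their direction and lie within 1 SD by construction, since a called probe passed the limit on both arrays. The largest changes were those of CUST_651_PI401301547 from -4.06 to -1.79 and CUST_736_PI400645798 from -4.11 to -2.41 with median centring, and of CUST_1343_PI401301547 over the VO-array CTRL RNA from -2.18 to -3.61 with processed signals. Same-dye comparisons and quantile normalisation over the 8 channels or over the diet channels alone were chosen after seeing the data. Aquantile leaves ratios unchanged by construction and is in none of these tallies, and where leaving out an array of either pair leaves the same arrays the value is counted once. No value was possible for the gene lists (no gene names), for the slide (1 slide, 1 scan), for the authors' value table in same-dye comparisons (ratios only) or for the error-model p-value across arrays. No paired analysis was possible because the results come from no test. Dim probes limit the rest, since 55.4% to 75.6% of probes were well above background in a channel.

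Median centring without loess moved 8 of the 12 counts, and the 2-fold limit moved 11. It gave 1068 higher for 66VO over CTRL, 2810 higher and 7 lower for VO over CTRL, and 4212 higher and 382 lower for VO over 66VO. Within a dye it gave 32 higher and 2333 lower for 66VO over VO, and 1538 lower for CTRL over CTRL. The correlation became 0.146. The share of higher calls went from 49.6% to 21.7%, from 71.7% to 99.8% and from 48.1% to 91.7% for these ratios, and in the same dye from 90.5% to 1.4% for 66VO over VO and from 44.5% to 68.2% for CTRL over CTRL. The centre then includes probes that are not compared: for VO over CTRL the median of the compared probes moved from 0.02 to 0.52 and that of the others lay at -0.49. For 66VO over CTRL it moved from -0.04 to -0.47.

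Feature Extraction's processed signals gave 308 higher and 168 lower for VO over CTRL, and the values deposited by the authors gave 308 and 169. Within a dye the processed signals gave 404 and 305 for 66VO over VO (57.0% higher against 90.5%), and 642 and 781 for 66VO over the VO-array CTRL RNA (45.1% against 76.0%). Without background correction, 81 were lower for VO over CTRL, 36 for 66VO over VO and 275 for 66VO over the VO-array CTRL RNA. An offset of 16 gave 49 lower for 66VO over VO, and no filter on dim probes 330 higher. Quantile normalisation gave 85 lower for VO over CTRL and 176 lower for 66VO over the VO-array CTRL RNA (65.4% higher against 76.0%). The cause was not tested for these.

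Limits of size act by construction. At 2-fold there were 1773 higher and 1685 lower for 66VO over CTRL, 49 and 13 for VO over CTRL and 1555 higher for VO over 66VO. Same-dye counts were 74 and 1 for 66VO over VO, 129 and 14 for 66VO over the VO-array CTRL RNA, and 1613 and 2006 for CTRL over CTRL. With the limit on the mean of the pair, 106 were lower for VO over CTRL, 61 for 66VO over VO and 203 for 66VO over the VO-array CTRL RNA. On single arrays, with the other left out, VO over CTRL gave 258 to 339 higher and 187 to 193 lower, since 1 array meets the limit more easily than 2. In the same dye, 66VO over VO gave 334 to 378 higher and 98 to 156 lower, and 66VO over the VO-array CTRL RNA gave 238 to 316 lower.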

Other observations

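The tests in this part were chosen after the results were seen. Most of the 14 probes at least 8-fold higher in VO than in CTRL were also higher in the 66VO-array CTRL RNA than in the VO-array CTRL RNA, namely 13 of them, with log2 differences from -1.86 to 4.18 over all 14. In 66VO the 14 probes were 3.37 to 6.24 higher than in the VO-array CTRL RNA. So 13 of the 14 were lower in the VO-array CTRL RNA than in each of the other 3 RNAs, and CUST_1002_PI400645798 was lower still in the 66VO-array CTRL RNA. These counts are by sign, and CUST_1274_PI401301547 differed by only 0.37 between the RNAs labelled CTRL. The 14 probes form only 5 groups by contig and shared sequence, so they are not separate observations. By the 1.5-fold rule 25.8% of all compared probes were higher in the 66VO-array CTRL RNA. Over all 129 probes called higher in VO, the median log2 difference of the 66VO-array CTRL RNA from the VO-array CTRL RNA was -0.93, and over the 51 called lower it was -2.41.

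Contigs whose identifiers start alike differed in their ratios of 66VO over the 66VO-array CTRL RNA. The meaning of these starts is not given in the sources used here. The median log2 ratio was 0.48 over 1006 probes with the start sbdiet, 0.39 over 957 with gsgl, 0.34 over 464 with gsgi and 0.31 over 1209 with gsgy. It was -0.13 over 5140 probes with cdn, -0.2 over 237 with gsug and -0.23 over 176 with gsub. For VO over CTRL these medians lay between -0.01 and 0.07, and the share of called probes ran from 0.6% for gsub and cb to 5.4% for gsgi, with 1.0% for cdn. The correlation of the ratios with the GC content of the probes was 0.091 for 66VO over CTRL and -0.136 for VO over CTRL.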
